A study of Mus musculus with 12 samples.

How the data were processed

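The series held 12 ChIP-seq libraries from cell lines of mouse pancreatic cancer, and 11 of them came with a region list used here. The remaining library, from the female WT line, is named as input in its title and as IgG in its antibody field, and had no list used here. Groups were taken from the antibody, sex and genotype in the labels, which gave 1 library per group. No label spoke of separate cultures. Libraries were prepared by Illumina's procedure and read on a Genome Analyzer, per the labels' protocols.

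Per the submitters' processing notes, Bowtie 1.1.2, SICER 1 and the mouse build mm9 were used, without a stated role for each. The deposited lists hold a chromosome, a start, an end and a whole number per region, which was taken as the count of reads in the region. That reading rests on the values and on the layout of SICER islands, since neither a header nor a label names the column. All region borders lay on steps of 200 bp. The smallest gap between regions was 400 bp, except 600 bp for H3K27ac and 800 bp for H3K27me3. These gaps differ by mark, so lists of different marks were made with different joining of neighbours. The control library behind each list, the significance threshold and the number of mapped reads were not given in the sources used here. Regions were called per library, and a region missing from a list may still hold signal below the threshold. Counts in regions depend on library depth and on the threshold, so they were used to rank regions within a list and not read as levels between lists. Summed over lists, they served only to order the regions shared by the 4 binding lists and to sort merged H3K4me1 regions into classes.

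Starts in the lists count from 0 and ends give the last base; positions are printed counting from 1, in mm9. No list held a region on the Y chromosome, the male lines included. The reference table at hand describes another build, GRCm38, and on 10 of 20 chromosomes listed regions reached beyond the last gene end of that table. For that reason no gene was assigned to any region. Gene lists fixed before the data were examined were not used, and regions are given by position. The rule for named regions, fixed before the data were examined, took the 5 regions per direction with the most reads in their own list among those with no overlap in the other genotype; the text gives the leading ones in full and the rest as counts or ranges. Broad domains were chosen by covered length.

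A region counted as shared when at least 1 bp overlapped a region of the other list. Shares carry exact Clopper-Pearson intervals at 95% over regions, which are not replicates. With 1 library per group there was no test between libraries, and no p-value was computed. Chance overlap was the mean of 1000 rotations of a list along each chromosome, over the span between the outermost regions of all lists (2569 Mb in total). That span includes stretches to which reads cannot be mapped, so the ratio to chance is somewhat too high. For the comparison between sexes, the 4 H3K4me1 lists were merged and each merged region scored as present or absent per list. The odds ratio of absence from the female and the male KO list was taken among regions present in both WT lists. The corresponding odds ratio for gain, although planned, has no meaning among merged regions because those absent from all 4 lists are not in the table; the overlap of regions found in KO alone was set against rotation in its place. Length classes were 3 classes of about equal size per list, and strata for the odds ratio were 10 classes of length or of reads.

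Alternatives fixed before the data were examined were a minimum overlap of 50% of the region, the upper part of each list by reads, autosomes alone, lists cut to the same number of regions, regions within 5 kb merged, uniform placement (100 draws) in place of rotation, and domains joined within 12.5 kb and kept above 20 kb. Leaving out chromosomes 1, 6, 15, 17 and 19, and the strata for the odds ratio, were chosen after seeing the data.

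Overlaps were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and overlap counts were checked against bedtools 2.31.1. Figures were drawn with matplotlib 3.10.9. The overlap and rotation steps were tested on simulated data made from the real region lengths. For KDM6A, a planted excess overlap of 30.5% over 2832 regions came back as 30.5%, and for H3K4me1 of the female lines 30.0% over 50982 regions came back as 29.8%. The simulated regions were placed at random along their chromosomes. Their chance share came from rotation against the regions known not to be planted, which real lists do not offer. The test therefore does not show how well rotation gives chance for the real lists.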

Results

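Chromatin immunoprecipitation with sequencing was carried out on cell lines from mouse pancreatic tumours, grown in F12/DMEM medium with EGF and not treated. The lines were labelled KDM6A-KO or KDM6A-WT and female or male. KDM6A is an X-linked demethylase of H3K27me3 and a subunit of the complexes built around the H3K4 methyltransferases MLL3 and MLL4. All labels, those with the WT genotype included, describe the line as established from a tumour without Kdm6a, so KO and WT are used here as the genotype field gives them. The region lists covered KDM6A and MLL4 in the female KO and WT lines and H3K4me1, the mark of enhancers, in the KO and WT lines of both sexes. H3K4me3, found at promoters, H3K27ac, found at active elements, and the repressive mark H3K27me3 were listed in the female WT line. Each group held 1 library, so no difference within a sex has a replicate check; H3K4me1 alone was listed for a second pair of KO and WT lines, the male one. The 95% exact binomial intervals in brackets cover counting error only. Reads inside the listed regions numbered from 108165 for MLL4 in WT to 17526099 for H3K4me3. The total depth of each library was not given in the sources used here.

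KDM6A regions were compared between the female KO and WT lines, with the KO line taken as the background of the antibody. The KO line held more KDM6A regions than the WT line, 5961 against 2847, and they covered 9.68 Mb against 4.21 Mb. The positions differed. Of the WT regions, 8.99% [7.97 to 10.1] were overlapped by a KO region, where rotation along the chromosomes gave 0.764%, and 4.36% [3.86 to 4.91] of the KO regions were overlapped by a WT region. Median length was 1400 bp in both lists. The 5 WT regions with the most reads and no KO counterpart lay on chromosomes 15 and 19, led by chromosome 15, 99808201 to 99819600, with 395 reads, and chromosome 15, 64086201 to 64092800, with 243 reads. All 5 were overlapped by H3K4me1 regions in each of the 4 H3K4me1 lists, and 4 of them by H3K27ac and H3K4me3 of the WT line. Among KO regions without a WT counterpart, the leading ones were chromosome 13, 12988201 to 13005600, with 720 reads, and chromosome 14, 44048601 to 44056200, with 325 reads. MLL4 regions of the KO line overlapped 4 of these leading 5, and also 4 of the leading 5 WT regions without a KO counterpart. With both lists at the same number of regions, the shared part of the WT list was 5.41%.

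MLL4, taken here as the methyltransferase KMT2D, was compared in the same lines. The KO line held 13152 MLL4 regions over 19.8 Mb and the WT line 2130 regions over 3.53 Mb, a ratio of 6.17 in number. Of the WT regions, 28.3% [26.4 to 30.3] were overlapped by a KO region, against 1.47% by rotation, and 12525 of the KO regions had no WT counterpart. Shared WT regions had a median of 49 reads and those without a KO counterpart 42. All 5 leading MLL4 regions found in WT alone lay on chromosome 15, the leading one at 78358001 to 78364000 with 214 reads, and all 5 carried H3K4me1 in the 4 lists of that mark together with H3K27ac and H3K4me3 of the WT line. The leading MLL4 region found in KO alone was on chromosome X, 166407401 to 166425600, with 929 reads, followed by chromosome 13, 12991601 to 13004200, with 509 reads, which lies inside the leading KDM6A region of the KO line. All 5 leading MLL4 regions of KO alone were overlapped by KDM6A regions of the KO line, taken above as background. Those on chromosomes 14 and 11 overlapped H3K4me1 of female KO, and the others did not. With both lists at the same number of regions, 10.8% of the WT regions were shared.

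The KDM6A and MLL4 lists were unevenly spread over the chromosomes. The chromosomes with the largest surplus differed by line and were the same for both antibodies. In the KO line, chromosomes 1, 6 and 17 held 56.2% of the KDM6A regions and 52.5% of the MLL4 regions. In the WT line, chromosomes 15 and 19 held 39.6% of the KDM6A regions and 40.7% of the MLL4 regions. Relative to its span, chromosome 19 had 7.76 times its share of KDM6A regions and 7.24 times its share of MLL4 regions in WT, and chromosome 1 had 3.77 and 3.37 times its share in KO. The surplus ran along whole chromosomes. Bins of 10 Mb were set against the median bin of the autosomes among the other 15 chromosomes. In the KDM6A list of KO, all 42 bins of chromosomes 1, 6 and 17 lay above it. So did 40 of 42 in the MLL4 list of KO, and 16 of 16 bins of chromosomes 15 and 19 in each WT list. A smaller surplus on 15 and 19 was also present in the KDM6A list of KO. There the lowest bins held 14 and 26 regions against that median of 8, the last bin of each chromosome left out. Relative to span, chromosome 19 had 1.51 times its share of KDM6A regions in KO, and 0.870 times for MLL4. On its chromosomes of surplus each line had a lower share of regions with H3K27ac of WT. In WT, 23.0% [20.6 to 25.6] of the KDM6A regions on 15 and 19 overlapped H3K27ac against 49.8% [47.2 to 52.4] on the other 15 chromosomes, and for MLL4 the values were 28.5% and 75.0%. In KO, regions on 1, 6 and 17 gave 31.1% against 40.6% for KDM6A and 36.0% against 68.2% for MLL4. On the other line's chromosomes of surplus the share was low for KDM6A of KO on 15 and 19, at 29.3%. It was not lowered for KDM6A of WT on 1, 6 and 17, at 58.7%. MLL4 stayed near its values on the other 15 chromosomes. It gave 67.4% in KO on 15 and 19 and 74.6% in WT on 1, 6 and 17. On those other 15 chromosomes the KO line still held more regions, 2203 against 1416 for KDM6A and 5703 against 1023 for MLL4. The shared part of the WT lists there was 7.56% for KDM6A and 34.5% for MLL4, a set of chromosomes chosen after the values were seen.

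**Figure D1:**
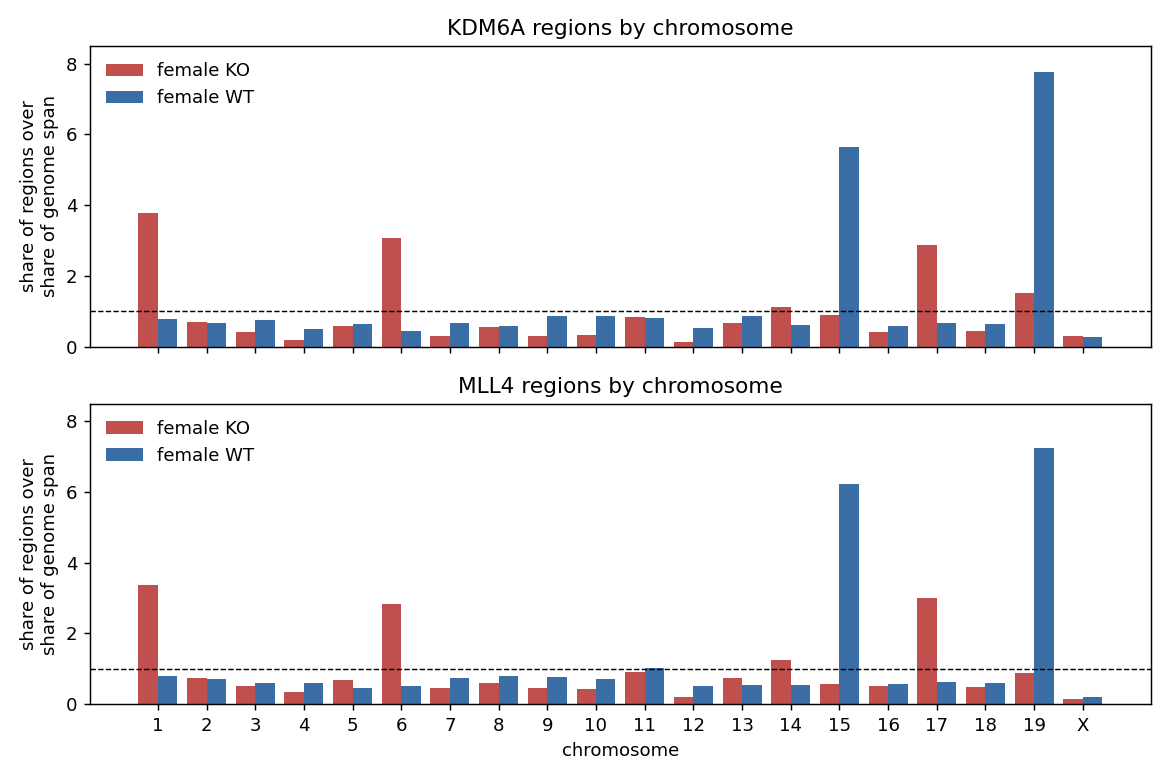
Share of the regions of each list on a chromosome divided by the chromosome's share of the genome span (vertical axis, ratio) for each chromosome (horizontal axis), for KDM6A (upper panel) and MLL4 (lower panel) in the female KO and WT lines, 1 library each; the dashed line marks an even spread. Chromosomes 1, 6 and 17 stand out in KO, and 15 and 19 in WT, where KDM6A reaches 7.76 on chromosome 19.

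The H3K4me1 lists asked whether the enhancer mark differed by genotype in the female lines. The KO line held 35041 H3K4me1 regions over 153.5 Mb and the WT line 56076 over 228.7 Mb. Of the WT regions, 48.9% [48.5 to 49.3] were overlapped by a KO region, and 76.6% [76.1 to 77.0] of the KO regions by a WT region; rotation gave 10.6% and 16.5%. This left 28658 regions listed in WT alone and 8213 in KO alone. Shared WT regions were longer than the others, with a median of 3400 bp against 2400 bp, and held more reads, with a median of 126 against 77. The WT region with the most reads and no KO counterpart spanned chromosome 1, 74033601 to 74118400, with 7489 reads over 84.8 kb; it overlapped KDM6A and MLL4 regions of WT and an H3K4me1 region of male WT, and no region of the male KO list. Next came chromosome 9, 48469201 to 48576000, with 6782 reads, its neighbour at 48576401 to 48643200 with 3483 reads, and chromosome 10, 70577201 to 70620200, with 2824 reads and 39770201 to 39828600 with 2770 reads. In the other direction the regions were shorter, led by chromosome 6, 91316801 to 91342800, with 2192 reads, and chromosome 14, 44048601 to 44067200, with 1539 reads, at the position named above for KDM6A. All 5 leading female KO regions were also covered by H3K4me1 in both male lines.

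In the male lines the KO list of H3K4me1 was again the shorter, and a larger part of the WT list was shared. Male KO held 49780 regions over 196.6 Mb and male WT 64247 over 259.1 Mb. Of the male WT regions, 58.0% [57.6 to 58.4] were shared with KO, against 14.3% by rotation, and 74.6% [74.2 to 75.0] of the KO regions were shared with WT, leaving 26971 in WT alone and 12637 in KO alone. Chromosome 11, 81813801 to 81856400, led the regions of male WT alone with 3920 reads. The next was chromosome 1, 74068601 to 74119800, with 3727 reads, overlapping the interval that led in the female lines, followed by a neighbouring pair on chromosome 7, 81511201 to 81549200 with 3047 reads and 81549801 to 81590800 with 2686 reads. The leading 5 regions of male KO alone ran from chromosome 15, 25794401 to 25811800, with 1252 reads to chromosome 14, 12439801 to 12451200, with 878 reads, and all 5 were overlapped by H3K4me1 of female WT.

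**Figure D2:**
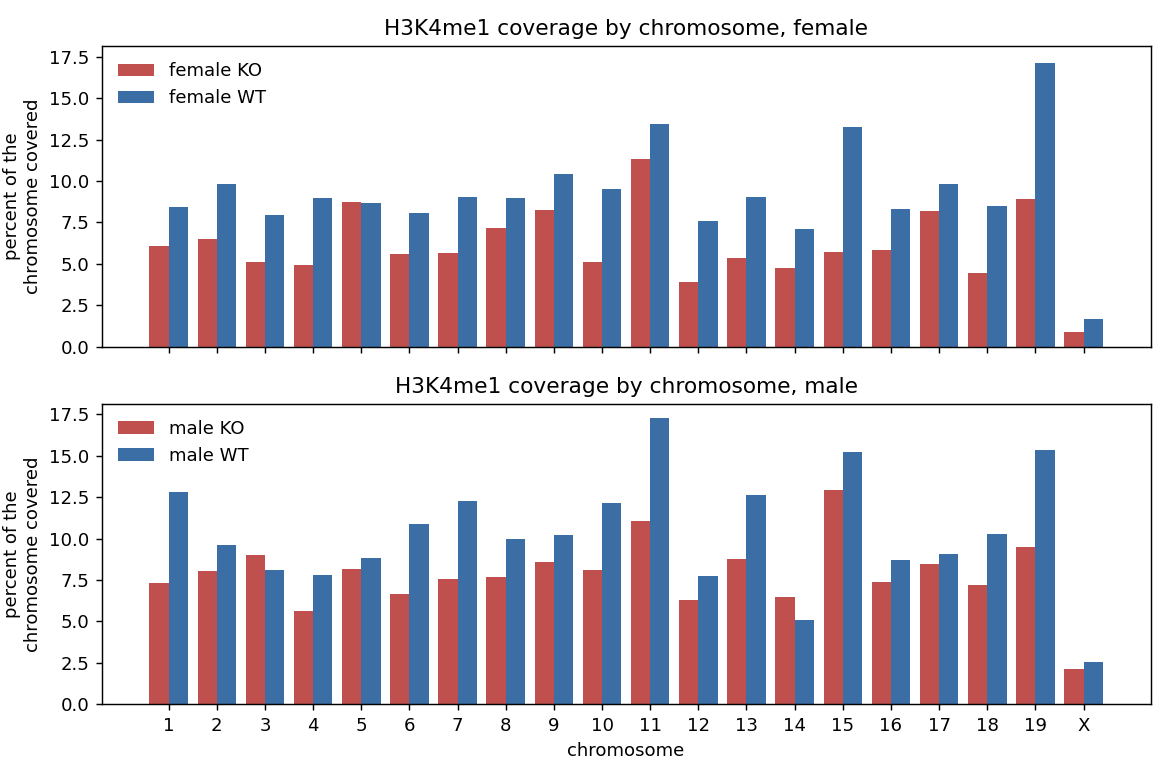
Percent of each chromosome's span covered by H3K4me1 regions (vertical axis) in the KO and WT lines for each chromosome (horizontal axis), female above and male below, 1 library per bar. Coverage was lower in KO on most chromosomes; female chromosome 15 went from 13.3% in WT to 5.73% in KO.

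Neighbouring H3K4me1 regions were joined into domains, as is done to find super-enhancers, and those above 20 kb were kept. Female WT had 5197 and female KO 3135 of them, male WT 6138 and male KO 4371. In female WT, 727 domains contained no H3K4me1 region of KO, against 62 domains the other way; in the male lines the numbers were 501 and 77. By covered length, chromosome 9, 48453401 to 48669200, led the female WT domains without any KO region. The domain at chromosome 7, 81480401 to 81710200 in female WT and 81499201 to 81849200 in male WT, was among the leading 5 in both sexes, as was chromosome 6, 118853001 to 119060000 in female WT and to 119010200 in male WT.

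The part of the H3K4me1 landscape shared between genotypes was mostly the part with active marks. Female WT regions overlapped by H3K27ac of the same line were shared with KO in 82.3% of cases [81.9 to 82.8], those without H3K27ac in 18.7% [18.3 to 19.2]. For H3K4me3 the values were 86.8% and 25.2%. H3K27me3 went the other way, with 39.1% [37.9 to 40.3] of its regions shared and 50.1% [49.7 to 50.6] of the rest. Male WT regions sorted by the same female marks gave 91.6% with and 32.9% without H3K27ac, 95.5% and 39.0% for H3K4me3, and 43.1% and 60.5% for H3K27me3. The contrast by H3K27ac was present among short, middle and long female regions alike, at 79.6% against 17.1%, 80.8% against 18.8% and 84.8% against 22.7%. Regions found in KO alone were richer in promoter marks than those in WT alone: H3K4me3 of female WT overlapped 30.4% [29.4 to 31.4] of the female KO regions and 9.90% [9.56 to 10.3] of the female WT regions, and in the male lines 33.1% and 3.56%. The marks were listed for the female WT line alone, so their state in KO and in the male lines is not known from these lists.

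**Figure D3:**
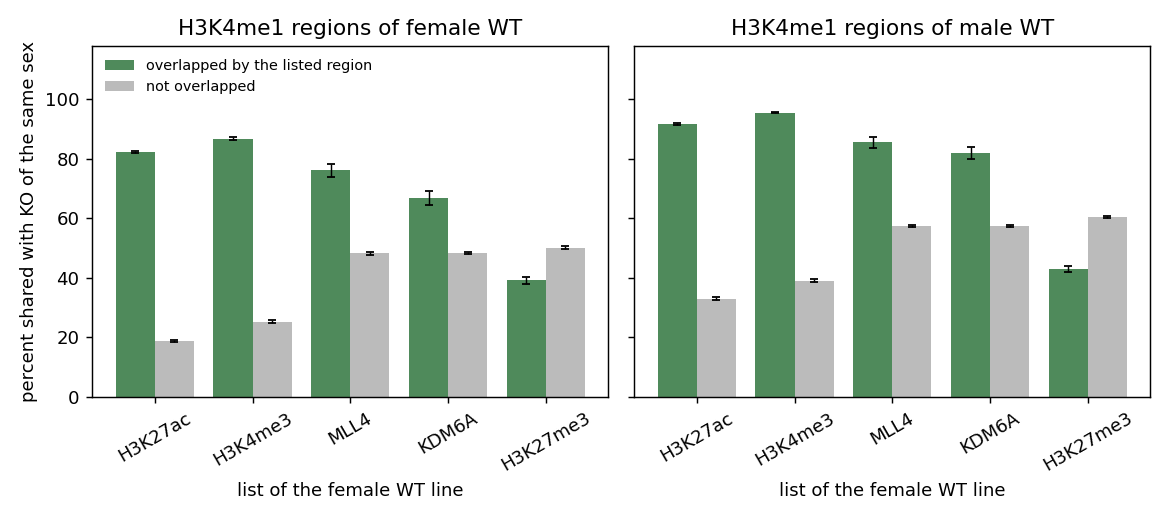
Percent of H3K4me1 regions of female WT (left) and male WT (right) shared with the KO line of the same sex (vertical axis), for regions overlapped by a region of each female WT list (green) or not (grey); error bars are 95% exact binomial intervals within 1 library. Regions with H3K27ac were shared in 82.3% and 91.6% of cases, regions without it in 18.7% and 32.9%.

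Whether the genotype difference fell on corresponding regions in both sexes was read from 77333 merged H3K4me1 regions, of which 18561 were listed in all 4 lines. Among the 35360 present in both WT lines, 43.8% were absent from female KO and 29.9% from male KO. Absence from both KO lists was found for 9275, where independence gives 4636. Of those absent from female KO, 59.9% were absent from male KO, against 6.55% of those kept in female KO. The odds ratio was 21.3, with a mean of 1.02 and a highest value of 1.30 over 1000 rotations. Regions of KO alone also met more than by rotation: 23.2% [22.3 to 24.1] of the female ones were overlapped by male ones, against 2.45%. At the same time, 49.4% of the female KO regions without a female WT counterpart were overlapped by a male WT region. With at least 50% of a region covered the odds ratio was 9.86. Within classes chosen after the values were seen it was 16.2 for reads in WT, 14.0 for length and 6.70 for reads summed over the 4 lists, which include the KO reads that absence itself removes.

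At the KDM6A regions of female WT, H3K4me1 was listed less often in the KO line. H3K4me1 of WT overlapped 61.5% [59.7 to 63.3] of the 2847 regions and H3K4me1 of KO 38.6% [36.8 to 40.4], a difference of 22.9 percentage points. Leaving out the KDM6A regions also found in KO gave 59.9% and 36.0%. Rotation of all 2847 regions gave 14.4% for WT and 8.38% for KO. The whole H3K4me1 list of female KO held 0.625 times the regions of WT. The difference was therefore not shown to be particular to KDM6A regions. The H3K4me1 regions of WT that overlapped KDM6A were shared with KO in 66.8% of cases [64.5 to 69.0], above the 48.3% [47.9 to 48.8] of all other H3K4me1 regions. Those overlapped by the KDM6A list of the KO line, taken here as the background of the antibody, were shared in 82.1% [80.5 to 83.5] against 47.3%. For the WT list this depended on length: among long regions the values were 75.4% and 64.5%, among middle ones 45.5% for both, and among short ones 30.4% [23.1 to 38.5] and 38.1% [37.4 to 38.7]. For MLL4 the H3K4me1 regions overlapped were shared in 76.2% of cases against 48.2%, and were above the others in each length class. With all lists at the same number of regions the difference between WT and KO was 7.80 percentage points. The cut H3K4me1 lists lower both shares by construction.

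About as many MLL4 regions found in KO alone lay inside H3K4me1 present in both genotypes as outside it. Of these 12525 regions, 50.7% [49.9 to 51.6] overlapped such H3K4me1, against 6.84% by rotation, while 4.05% [3.71 to 4.41] overlapped H3K4me1 found in KO alone, against 1.44%. On the 15 chromosomes without the surplus the values were 68.3% and 4.23%, and for the 6748 regions on chromosomes 1, 6 and 17 they were 36.2% [35.1 to 37.4] and 4.02%. H3K4me1 found in WT alone overlapped 6.50% [6.07 to 6.94] of the 12525 regions, against 4.97% by rotation. MLL4 regions of both lines were overlapped by H3K4me1 of both genotypes in 93.1% of 627 cases. Among the 1527 MLL4 regions of WT alone, 34.7% [32.3 to 37.2] overlapped H3K4me1 of both genotypes, 21.3% [19.3 to 23.4] overlapped H3K4me1 of WT alone, against 6.66% by rotation, and 0.589% overlapped H3K4me1 of KO alone. The share of 4.05% moved with the definition of a region, from 2.69% with neighbours within 5 kb merged to 8.38% with at least 50% coverage, 7.27% in the upper part of each list by reads and 14.9% with lists of the same number of regions.

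The 6 lists of female WT described the chromatin around KDM6A and MLL4. KDM6A regions were overlapped by MLL4 in 13.4% of cases [12.2 to 14.7], against 0.858% by rotation, and MLL4 regions by KDM6A in 17.7% [16.1 to 19.4]. H3K27ac overlapped 40.1% of the KDM6A and 56.0% of the MLL4 regions, and H3K4me3 28.9% and 44.7%. The regions of both antibodies overlapped H3K27me3 less than by rotation, at 6.25% [5.39 to 7.20] against 13.8% for KDM6A and 7.89% [6.78 to 9.11] against 14.1% for MLL4. The KDM6A list of the KO line gave nearly the same value, 6.26% [5.66 to 6.90] against 14.5%. Without chromosomes 1, 6, 15, 17 and 19 the WT lists gave 3.88% against 11.6% for KDM6A and 4.01% against 12.2% for MLL4. With lists of the same number of regions KDM6A of WT gave 2.02%. Cutting the H3K27me3 list lowers that overlap by construction, and no rotation was run on the cut lists. None of the 4 histone marks overlapped 34.1% of the KDM6A regions and 24.7% of the MLL4 regions. Among the marks themselves, 84.2% of the H3K27ac regions overlapped H3K4me1 and 65.0% H3K4me3, and 7.44% overlapped H3K27me3, 0.495 times the share given by rotation. In the KO line, MLL4 overlapped 33.1% [31.9 to 34.3] of the KDM6A regions, against 3.32% by rotation, and 25.2% [23.4 to 27.1] on the 15 chromosomes without the surplus. In the reverse direction KDM6A overlapped 15.4% [14.7 to 16.0] of the MLL4 regions of KO, against 1.54% by rotation. On the 15 chromosomes without the surplus it was 9.91% [9.14 to 10.7].

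**Figure D4:**
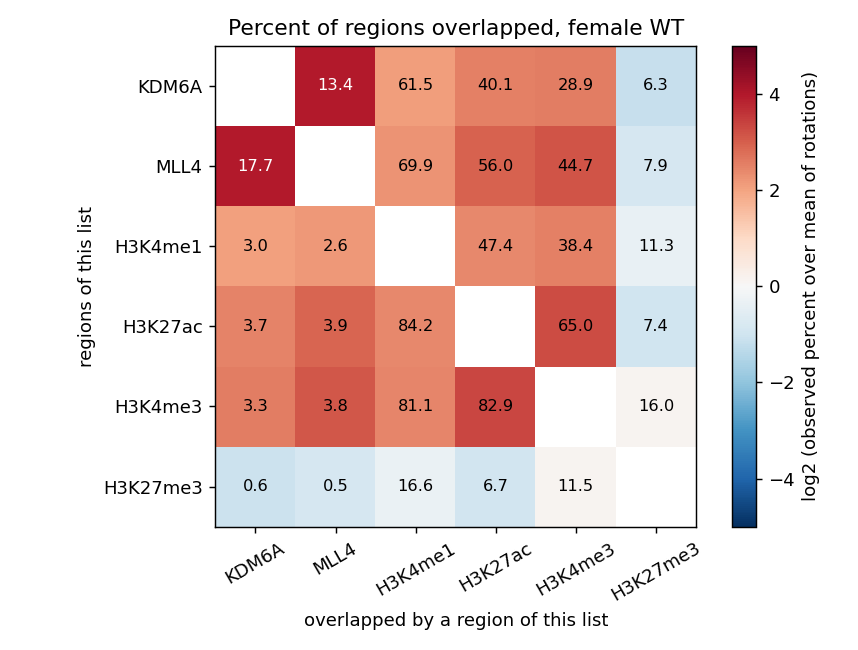
Percent of the regions of each female WT list (rows) overlapped by a region of each other list (columns), with colour for the log2 ratio of that percent to the mean of 1000 rotations; 1 library per list. KDM6A and MLL4 overlap each other at 13.4% and 17.7%, and both lie below the rotated mean in H3K27me3.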

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

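The tests on chromosome copy number, on H3K27ac at the chromosomes with a surplus, on swapped labels and on the KDM6A antibody in KO were chosen after their results were seen.

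H3K4me1 coverage by chromosome went in opposite directions in the 2 sexes on 3 chromosomes; with 1 library per group the difference was not tested. KO over WT covered length was 0.644 in female and 1.11 in male on chromosome 3, 1.01 and 0.925 on chromosome 5, and 0.665 and 1.27 on chromosome 14.

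The KDM6A and MLL4 regions concentrated on chromosomes 1, 6 and 17 in the KO line and on 15 and 19 in the WT line. Preferred binding at active elements was argued against as the whole cause in WT. H3K27ac overlapped 23.0% of the KDM6A and 28.5% of the MLL4 regions of WT on 15 and 19. On the other 15 chromosomes it overlapped 49.8% and 75.0%. A part cannot be excluded, because a lower share does not count regions per active element. The KO line on 1, 6 and 17 was not part of this test. Extra copies of these chromosomes in each line stay open as a candidate explanation. The female H3K4me1 lists leaned that way on 5 of the 5 chromosomes, with KO over WT covered length above the median of 0.644 of the other 15 on 1, 6 and 17 and below it on 15 and 19, but 1 of the 5 alone, chromosome 15, lay outside the range of the other 15 (0.514 to 1.01). The 5th percentile of reads per 200 bp among listed regions lay above the median of the other 15 chromosomes on 15 and 19 in every list, both KO lines included. For MLL4 of WT it was within their spread, at 1.03 times on both against 1.04 on chromosome 4. The same held on 15 for KDM6A and MLL4 of KO, where chromosome 12 was higher. The percentile was above all of the other 15 on 19 in both KO binding lists, and on both for KDM6A of WT. For H3K4me1 it was 1.12 times the median of the other 15 chromosomes on both in female KO. In male KO it was 1.06 times on 15 and 1.18 times on 19. On 1, 6 and 17 it was near that median. What this means for copy number was not tested. Neither copy number nor the control behind each list was known here.

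There were fewer H3K4me1 regions in KO than in WT in both sexes. A higher detection limit in KO that drops the regions with the fewest reads was argued against as the whole cause. Of the 25% of WT regions with the most reads, 17.6% in male and 30.1% in female were missing from KO. The prediction was under 5%. Of the 25% with the fewest reads it was 62.2% and 66.9%. Reads in a region can grow with its length, so a limit on read density was not tested. A copy number difference on the 5 chromosomes was also argued against as the whole cause, with KO over WT numbers of 0.797 in male and 0.631 in female lines without them. These 5 were picked from the female KDM6A and MLL4 lists. Copy number on other chromosomes or in the male lines was therefore not addressed. A change by genotype may account for part of it, as absence from KO coincided between the sexes with an odds ratio of 6.70 within classes of reads summed over the 4 lists, KO included, 14.0 within classes of length and 16.2 within classes of WT reads. It cannot be told apart from other differences between the KO and WT lines or libraries, because each genotype and sex has 1 line and 1 library.

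More KDM6A antibody regions were listed in the KO line than in the WT line. A swap of the labels of the KDM6A libraries alone was argued against by the chromosome profile. Spearman's rho of the KDM6A list of KO over 20 chromosomes was 0.952 with MLL4 of KO and 0.268 with MLL4 of WT, a difference of 0.684. The same values would arise if KO and WT were swapped for both antibodies, so that case was not addressed. The surplus on chromosomes 1, 6 and 17 was not the whole cause either, as the KO list was still 1.56 times as long without the 5 chromosomes. Pull-down of active chromatin without the target protein may contribute and stays open: outside these chromosomes 47.2% of the KDM6A regions of KO lay in H3K4me1 of the KO line, above the 8.26% given by rotation and near the 47.5% of the WT regions in that same list, but below the 70.4% of the WT regions in H3K4me1 of their own line. Protein left in the line labelled KO was not tested and could give similar values. The listed KDM6A regions of KO held fewer reads per 200 bp than those of WT, with a median of 5.78 against 7.00. The 5th percentile was 4.75 against 5.67. These values describe the lists and not levels of binding. Whether another threshold or depth gave the longer KO list was not tested.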

How the results depend on the processing

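No paired analysis was possible because the groups share only replicate number 1. A comparison of H3K4me1 blocked by sex would rest on 2 pairs and was not run; KO over WT numbers were 0.625 in the female and 0.775 in the male pair. The odds ratio between sexes and the KO over WT numbers of regions stayed on their side of 1, and the percentage-point differences stayed above 0, under each setting run; percents of regions have no direction to change. In all, 32 alternatives of the main comparisons stayed within their intervals (or within 1.5 times for numbers of regions), those on autosomes alone included. The values below lay outside the range set for each, in percent of regions unless stated. With at least 50% covered, the shared part of the WT list was 7.02 for KDM6A, 24.3 for MLL4 and 42.6 (female) and 51.0 (male) for H3K4me1, the odds ratio between sexes 9.86, MLL4 of KO alone in H3K4me1 of KO alone 8.38 and KDM6A with MLL4 in WT 11.5. In the upper part of each list by reads, KDM6A gave 6.96, H3K4me1 46.7 (female) and 55.3 (male), the odds ratio 17.5, H3K4me1 at KDM6A regions 26.5 percentage points and MLL4 of KO alone 7.27. With lists of the same number of regions, KDM6A gave 5.41, MLL4 10.8, H3K4me1 57.0 (female) and 64.0 (male), the odds ratio 15.9, H3K4me1 at KDM6A regions 7.80 points, MLL4 of KO alone 14.9 and KDM6A with MLL4 15.1. Merged within 5 kb, H3K4me1 gave 52.1 (female) and 61.7 (male), the odds ratio 23.9 and MLL4 of KO alone 2.69. Domains above 20 kb gave 46.7 (female) and 53.6 (male). Of the settings chosen after seeing the data, leaving out chromosomes 1, 6, 15, 17 and 19 gave 7.56 for KDM6A, 34.5 for MLL4 and 59.0 for male H3K4me1, and the odds ratio was 14.0 within classes of length, 6.70 of reads and 16.2 of WT reads. Lists of the same number hold fewer regions by construction; for the other shifts the cause was not tested. Of the remaining values, 12 stayed within their range, uniform placement included, and 11 moved, among them KDM6A with H3K27me3, from 6.25 to 2.02 with lists of the same number and to 3.88 without the 5 chromosomes. The window around transcription starts was not run, as no gene was assigned. Unknown library depth and thresholds limit every comparison of list lengths.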

Other observations

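The values in this part belong to no planned comparison and were all chosen after seeing the data. In female WT, 3924 H3K4me3 regions (16.0% [15.6 to 16.5], 14.4% by rotation) also overlapped H3K27me3, the combination known from bivalent promoters. By length the overlap lay below rotation, at 0.665 times its mean. They were shorter than the other H3K4me3 regions, with a median of 1800 bp against 2600 bp, and carried less H3K27ac, 47.3% against 89.6%. KDM6A regions of WT overlapped 0.765% of them and 3.75% of the other H3K4me3 regions, and MLL4 regions of KO 4.28% and 21.5%. H3K4me1 of male KO overlapped 82.6% of them, and that of the other 3 lines between 56.8% (female KO) and 63.4% (male WT). The male KO list was also the highest over the other H3K4me3 regions, at 92.4% against 81.8% to 86.7%. The H3K27me3 list held very broad domains, the longest at chromosome 15, 102555401 to 102922200, with 366.8 kb and 17226 reads. It was followed by chromosome 7, 86625001 to 86795000, with 170.0 kb.

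Only 59 of 20358 merged binding regions were listed in all 4 KDM6A and MLL4 lists. Of these, 57 overlapped H3K27ac and 53 H3K4me3 of female WT, 56 overlapped H3K4me1 of both female lines, and 24 lay on chromosomes 1, 6, 15, 17 or 19. That with the most reads summed over the lists was chromosome 19, 38093601 to 38111200, followed by chromosome 15, 61361401 to 61369600, and its neighbour at 61275801 to 61282400. By comparison, 1678 merged regions were listed in both KO lists alone and 182 in both WT lists alone.

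Chromosome X was sparsely covered in the lists of either sex. Its covered share was 0.127 of that of the autosomes for H3K27me3, 0.358 for H3K4me3 and 0.248 for H3K27ac of female WT. For H3K4me1 it was 0.178 in female WT, 0.144 in female KO, 0.243 in male WT and 0.266 in male KO. Differences in mappability and copy number between X and autosomes were not measured here.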
